A study of Homo sapiens with 9 samples.

How the data were processed

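The series holds 9 CUT&Tag libraries from A549 cells, a human lung adenocarcinoma line, in 3 groups of 3 replicates. CUT&Tag places a transposase at an antibody's targets in permeabilised cells, so that sequenced fragments come from bound sites. In the first group, cells whose own BAZ2B gene carries an HA epitope tag were profiled with an anti-HA antibody. In the second group, untagged wild-type cells were profiled with the same antibody. In the third group, the tagged cells were profiled with an antibody against H3K4me3. Groups were taken from the sample titles. The antibody field of H3K4me3 replicates 2 and 3 ends in another number than that of replicate 1, and the titles were followed. The labels' protocols also describe an siRNA transfection that no sample label assigns to a library, and the addition of 35 ng of Drosophila chromatin as a spike-in. Whether the spike-in was used to scale anything is not given in the sources used here.

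The authors deposited 1 peak list per group and no value per replicate. Reads were aligned with Bowtie2 2.4.5 and peaks were called with MACS2 2.1.4, with Picard, SAMtools 1.15.1 and bedtools also named, on the builds hg19 and dm6, per the submitters' processing notes. The MACS2 settings and any control library are not given in the sources used here. Per the labels, a peak was kept when it was present in at least 2 replicates, and the rows were taken from the largest of the replicates' peak files. The peak names in the deposited files show which replicate that was: replicate 3 for the tagged anti-HA group, replicate 2 for the untagged group and replicate 1 for H3K4me3. Every position, width and score is therefore that of 1 library, filtered by the others. The names of the untagged and H3K4me3 libraries carry the same extra tag, and those of the tagged anti-HA library carry none. What the tag stands for is not given in the sources used here. Whether the tagged library came from another run is not known, so an effect of the run on the comparison of the 2 lines is not excluded.

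The deposited fold enrichment of a peak is a ratio that the authors' peak caller computed over its own background estimate for that library. The deposited −log10 q value is the authors' significance of the peak, and its lowest value in the 3 lists was 1.36, just above the 1.30 that a q of 0.05 gives. Start, end and summit offset are positions in bp as deposited by the authors. Scores are not scaled between lists. They were used to rank and describe peaks within a list and, through ranks, to relate lists at matched peaks, and medians of different lists set side by side do not measure a change. The depth of the libraries is unknown, since the lists give no read counts, so numbers of peaks are not adjusted for depth. Intervals on shares of peaks are exact 95% binomial (Clopper-Pearson) intervals and cover counting error over peaks only.

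Peaks on chromosomes 1 to 22, X and Y were analysed, and those on other contigs were counted separately. Intervals that overlapped or touched within a list were to be merged, but none did. An overlap needed at least 1 bp. The share of one list that overlapped another was set against 1000 circular shifts of the other list within each chromosome, with a two-sided permutation p whose smallest possible value is 0.001. Chromosome lengths of hg19 came from GenomeInfoDb 1.38.1 and cytogenetic bands of hg19 from circlize 0.4.16. Shares of peaks were compared with Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over 24 chromosomes, and medians with 100000 permutations of the peaks, whose smallest possible p is 1e-05. In these tests the peaks are the units, not cultures: they describe these lists, and no test across replicates could be made. Peaks that matched one to one between 2 lists were compared by the Spearman correlation of their ranks. Common odds ratios over strata are Mantel-Haenszel estimates from statsmodels 0.14.6. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

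The tests were tried on simulated data. With the tagged peaks placed at random and the untagged list left as it was, 0 of 20 runs passed the threshold of 0.05. These runs used fewer shifts than the tests of the lists. Random placement does not keep the clustering of the real tagged peaks, so the runs do not cover 2 lists that cluster alike. With 30% of the tagged peaks placed on untagged peaks, all 20 of 20 runs passed and the mean measured share was 30.1%. The permutation test of medians passed in 1 of 20 runs with no difference and in 20 of 20 runs with a difference of 1 fold unit, over 6700 simulated peaks. Fisher's exact test passed in 20 of 20 runs for simulated shares of 99% and 95%, and was not tried without a difference. The lists themselves gave smaller differences, 0.43 fold units between medians and H3K4me3 shares of 98.8% against 99.4%. The simulations did not try the 2 tests at those sizes.

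The groups, the design's tests, their alternatives and the rule for named regions were fixed before the data were examined. Further tests were added later, and the closing observations name them. The rule named the 20 tagged-line peaks without an untagged peak that had the highest fold enrichment, the 5 highest shared peaks, the 5 highest untagged-only peaks, and the 5 highest tagged-only peaks without H3K4me3. Gene names are not reported, because gene positions on hg19 were not used here: the gene table at hand is on GRCh38, and positions were not converted. The planned tests of promoter share, G-quadruplex motifs and gene lists, and the values planned for BAZ2A and BAZ2B themselves, were left out for the same reason. Regions are given by 1-based hg19 position and cytogenetic band. The alternatives were a stricter q, autosomes only, unmerged rows, an overlap of at least 50% of the peak, peaks extended by 1 kb, lists of the same length, and random placement in place of shifts.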

Results

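CUT&Tag peaks were compared between 3 groups of A549 lung adenocarcinoma cells of 3 replicates each, with 1 peak list per group. BAZ2B is a bromodomain protein that serves as an accessory subunit of ISWI-type chromatin remodelers, and the series title places it in the control of G-quadruplex DNA. Cells with HA-tagged endogenous BAZ2B gave 7027 anti-HA peaks, of which 6794 lay on the assembled chromosomes. Untagged wild-type (WT) cells hold no HA epitope and so give the background of the assay with this antibody, whose source was not tested. They gave 2451 peaks, 2389 of them on the assembled chromosomes. The tagged cells gave 17630 peaks of H3K4me3, a histone mark of active promoters, 17018 of them on the assembled chromosomes. The HA-BAZ2B peaks covered 8.34 Mb with a median width of 1219 bp (interquartile range 872 to 1567 bp), the H3K4me3 peaks 19.8 Mb with a median of 1132 bp, and the WT peaks 1.61 Mb with a median of 639 bp. The median fold enrichment, as the authors' peak caller gave it, was 8.16 for HA-BAZ2B, 9.07 for H3K4me3 and 6.42 for WT. There was no value per replicate, so no number of peaks has a replicate error, and library depth was unknown.

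The filter for peaks seen in at least 2 replicates acted unequally on the 3 groups. Peak numbers in the source libraries ran to at least 21906 for H3K4me3, 16278 for HA-BAZ2B and 9696 for WT. At most 80.5% of the H3K4me3 peaks, 43.2% of the HA-BAZ2B peaks and 25.3% of the WT peaks of those libraries were thus kept. At least 9251 peaks of the HA-BAZ2B library and 7245 of the WT library were not. The difference in length between the anti-HA lists was not adjusted for depth or for recurrence.

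The comparison of tagged with untagged cells sets the anti-HA sites of the tagged line against those found without the tag. Of the 6794 HA-BAZ2B peaks, 1947 (28.7%, 95% interval 27.6 to 29.7%) overlapped a WT peak and 4847 did not. The latter are called HA-BAZ2B-only, which means without a listed WT peak. Such a site may still hold a WT peak that the filter for recurrence removed. Shifted WT lists overlapped 0.211% on average and 0.397% at most, and the excess was larger than in any of the 1000 shifts (permutation p = 0.001). Seen from the other side, 1935 of 2389 WT peaks (81.0%, 79.4 to 82.6%) overlapped an HA-BAZ2B peak, against 0.600% after shifting (permutation p = 0.001). With an overlap of at least 50% of the HA-BAZ2B peak, the share of HA-BAZ2B peaks on a WT peak was 13.8% (permutation p = 0.001).

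The strongest HA-BAZ2B peaks without a WT peak lay on 11 chromosomes and in every case on an H3K4me3 peak. The highest was at 20q11.21 (chromosome 20, 30102154 to 30102761), with a fold enrichment of 18.6 over 608 bp, on an H3K4me3 peak of 17.9. It was followed by 7q11.21 (chromosome 7, 64126389 to 64127040), with 17.98, and by 20p13 (chromosome 20, 1757330 to 1758125), with 17.6. Next came 8q21.13 (chromosome 8, 82597953 to 82598612), with 17.3, and 1q32.1 (chromosome 1, 201798256 to 201799067), also with 17.3. The peak at 19q13.33 (chromosome 19, 50879599 to 50880123) had a fold enrichment of 17.2 and the one at 1p36.33 (chromosome 1, 28812 to 29551) of 17.1. That last peak lay 28.8 kb from the end of its chromosome, and those at 16p13.3 (chromosome 16, 60026 to 60745; 16.2) and 10q26.3 (chromosome 10, 135462072 to 135462802; 16.3) were also close to one, at 60.03 and 71.9 kb. Over the 20 highest, fold enrichment ran from 15.5 to 18.6, width from 437 to 958 bp, and the H3K4me3 fold enrichment at the same place from 12.7 to 20.2.

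The highest tagged-line peaks shared with WT cells were at 9q22.31 (chromosome 9, 95639727 to 95640421; 18.99 in the tagged list), 19p13.3 (chromosome 19, 5790676 to 5791229; 17.7), 19q13.2 (chromosome 19, 41945439 to 41945894; 17.3), 19p12 (chromosome 19, 24269869 to 24270707; 17.1) and 1q21.1 (chromosome 1, 142890225 to 142891071; 16.9). In the WT list, these 5 sites had fold enrichments of 5.20 to 9.14. The sites were chosen by their tagged-line value, and the lists are not scaled to each other, so these values do not show a difference between the lines.

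Within the tagged list, peaks with and without a WT peak differed by small amounts. The median fold enrichment was 8.30 without and 7.87 with a WT peak, a difference of 0.43 (permutation test over peaks, p = 1e-05). The peaks without a WT peak were narrower, at 1194 against 1303 bp (difference -109 bp, permutation test, p = 1e-05). The difference in fold enrichment did not pass when an overlap had to cover 50% of the peak (0.14, permutation p = 0.275).

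WT peaks that had no HA-BAZ2B peak numbered 454, with a median fold enrichment of 5.55 and a median width of 500.5 bp, against 6.61 and 671 bp for the 1935 shared ones, a difference that was not tested. The highest was at 13q33.3 (chromosome 13, 110076336 to 110076802), with a fold enrichment of 19.1 and no H3K4me3 peak. It was followed by 17p11.2 (chromosome 17, 22020536 to 22020991), with 17.9, and by 7p22.3 (chromosome 7, 9849 to 10310), with 17.8 at 9.85 kb from the end of the chromosome. The remaining 2 of the 5 highest were at 9q21.11 (chromosome 9, 69710736 to 69711331), with 16.7, and 1p22.2 (chromosome 1, 91852727 to 91853142), with 16.6, both without an H3K4me3 peak.

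The H3K4me3 libraries served as a control of the assay in the tagged line, and they place the anti-HA sites relative to marked promoters. HA-BAZ2B peaks lay almost without exception on H3K4me3 peaks: 6725 of 6794 (98.98%, 98.7 to 99.2%) overlapped one, against 1.66% after shifting (permutation p = 0.001). WT peaks did so in 2232 of 2389 cases (93.4%, 92.4 to 94.4%), against 1.36% after shifting (permutation p = 0.001). The shifts, here and above, keep the spacing of the peaks but not the kind of sequence they lie in. Passing them shows that the lists share places, and since the untagged list passes too, it does not set tagged BAZ2B apart from the background. With both lists of a pair limited to the length of the shorter one, by highest −log10 q, the share was 63.4% for 6794 HA-BAZ2B and 6794 H3K4me3 peaks, and 29.0% for 2389 WT and 2389 H3K4me3 peaks (permutation p = 0.001 for both). These 2 shares rest on different numbers of H3K4me3 peaks and do not compare the lines. Conversely, 6729 of 17018 H3K4me3 peaks (39.5%, 38.8 to 40.3%) carried an HA-BAZ2B peak and 2227 (13.1%, 12.6 to 13.6%) a WT peak. The 1922 H3K4me3 peaks that carried both had a median width of 1419 bp, the 4807 with HA-BAZ2B only 1304 bp, the 305 with WT only 779 bp, and the 9984 with neither 984 bp.

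H3K4me3 peaks with a WT peak carried an HA-BAZ2B peak in 86.3% of cases (84.8 to 87.7%), and those without a WT peak in 32.5% (31.7 to 33.3%), an odds ratio of 13.1 (95% interval 11.5 to 14.8). With the H3K4me3 peaks grouped by their own fold enrichment and width into 49 strata, the common odds ratio was 15.8 (13.6 to 18.5).

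The absence of a WT peak did not mark a set outside H3K4me3. Of the 4847 HA-BAZ2B-only peaks, 4790 (98.8%, 98.5 to 99.1%) overlapped H3K4me3, and of the 1947 shared with WT, 1935 (99.4%, 98.9 to 99.7%) did, an odds ratio of 0.521 (0.279 to 0.973; Fisher's exact test, p = 0.0438). This difference did not pass among peaks with a −log10 q of at least 5 (odds ratio 0.324, p = 0.0564, Fisher's exact test), and its direction turned when an overlap had to cover 50% of the peak (odds ratio 1.07, Fisher's exact test, p = 0.759).

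The 57 HA-BAZ2B-only peaks without H3K4me3 were weak and narrow, with a median fold enrichment of 4.81 and a median width of 316 bp. They lay a median of 19.8 kb from the nearest H3K4me3 peak, and 39 were more than 10 kb away. The highest was at 10p15.1 (chromosome 10, 6443608 to 6443941), with a fold enrichment of 6.97. The next were at 8q24.21 (chromosome 8, 128822143 to 128822459), with 6.68, 19p13.11 (chromosome 19, 18490984 to 18491340), with 6.52, 3p24.3 (chromosome 3, 17746286 to 17746590), with 6.41, and 17q23.1 (chromosome 17, 57906424 to 57906717), with 6.13.

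Both anti-HA lists favoured H3K4me3 peaks with a high −log10 q and a large width, and the tagged list did so over a wider range. With the H3K4me3 peaks in 10 groups of nearly equal number by −log10 q, from the lowest to the highest group the share with an HA-BAZ2B peak went from 8.23% (6.96 to 9.63%) to 77.6% (75.5 to 79.5%). The share with a WT peak went from 7.34% (6.15 to 8.69%) to 30.4% (28.3 to 32.7%). By width, the shares went from 9.93 to 65.7% for HA-BAZ2B and from 6.93 to 25.6% for WT. By fold enrichment, they went from 28.3 to 42.3% for HA-BAZ2B, with a maximum of 44.1% in group 6, while the WT share went from 11.1% in the lowest group to a maximum of 16.04% in group 3, a minimum of 9.99% in group 9 and 11.05% in the highest group.

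**Figure D1:**
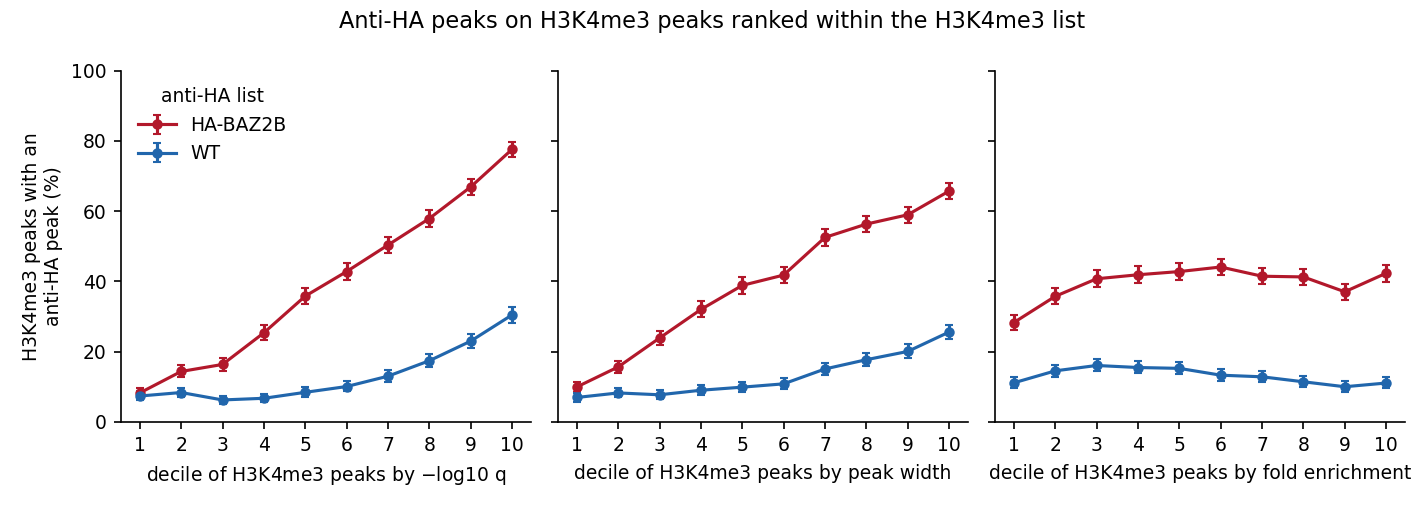
Share of H3K4me3 peaks (%, y axis) that overlap an HA-BAZ2B (red) or WT (blue) anti-HA peak, by deciles of the H3K4me3 list ranked by −log10 q, width or fold enrichment (x axes, 1 is the lowest); points are shares and bars are exact 95% binomial intervals over peaks. The HA-BAZ2B share goes from 8.23% to 77.6% over the deciles of −log10 q and the WT share from 7.34% to 30.4%.

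Where 1 anti-HA peak matched 1 H3K4me3 peak, the HA-BAZ2B peaks had nearly the width of the H3K4me3 peaks. Over 6556 such pairs, the HA-BAZ2B peak was a median of 0.918 times as wide as the H3K4me3 peak. Ranks of width correlated with a Spearman rho of 0.87 and ranks of fold enrichment with 0.74, across peaks, which are not independent replicates. Over 2210 pairs of WT and H3K4me3 peaks, the WT peak was a median of 0.502 times as wide. For these pairs, rho was 0.35 for width and 0.23 for fold enrichment. H3K4me3 was profiled only in the tagged cells, so the WT pairs join peaks of different lines and the HA-BAZ2B pairs do not. Summits lay a median of 84 bp apart for HA-BAZ2B and H3K4me3, against 283 bp for a random place in the same HA-BAZ2B peaks. For WT and H3K4me3 the distance was 78 bp, against 178.5 bp. Between HA-BAZ2B and WT peaks, over 1902 pairs, rho was 0.14 for fold enrichment and 0.29 for width.

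**Figure D2:**
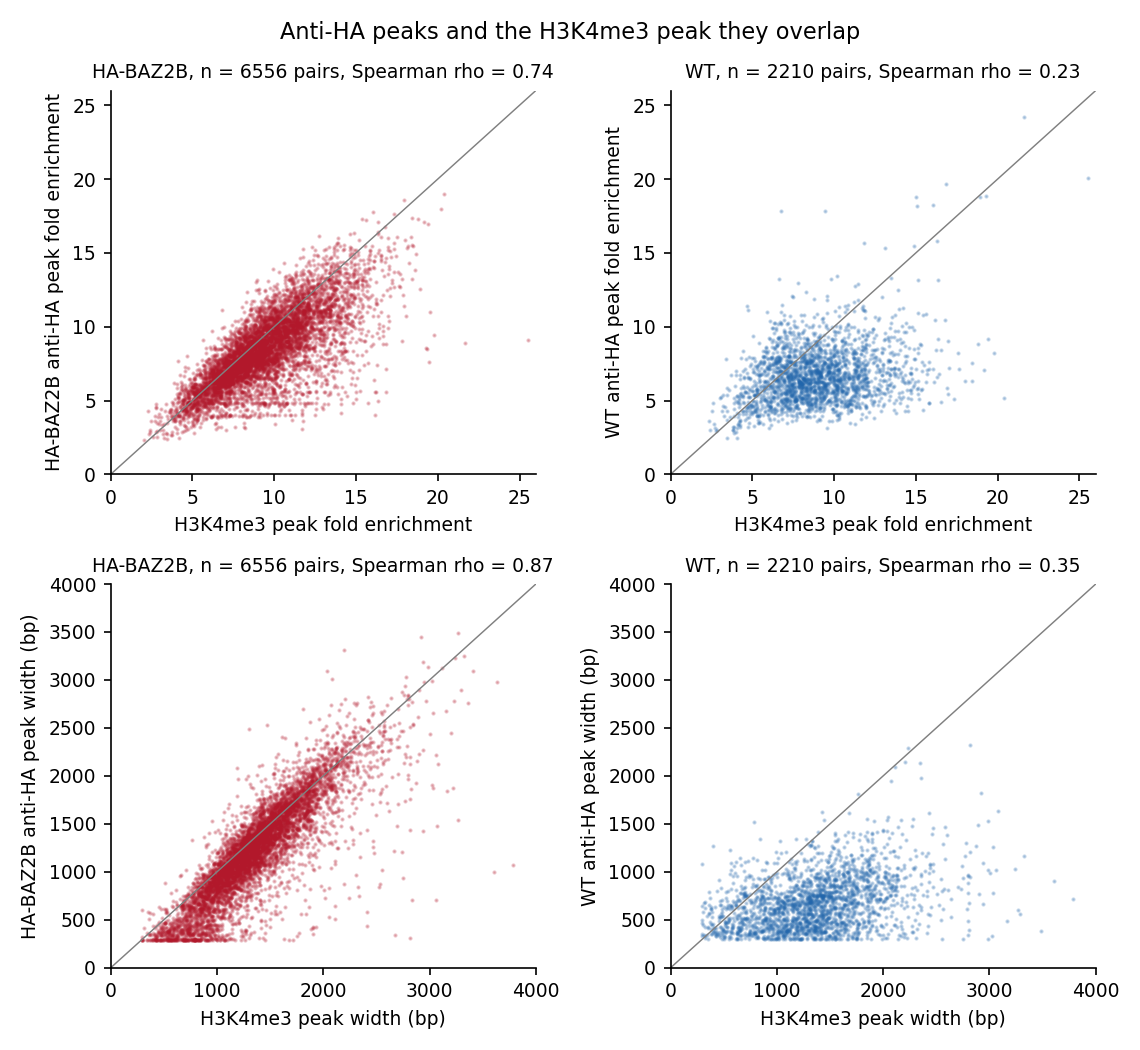
Fold enrichment (top) and width in bp (bottom) of anti-HA peaks (y axes) against the H3K4me3 peak they match one to one (x axes), for HA-BAZ2B (left, 6556 pairs) and WT (right, 2210 pairs); each point is 1 pair and the grey line marks equal values. HA-BAZ2B points follow the line (rho 0.87 for width), and WT points lie mostly below it (rho 0.35).

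HA-BAZ2B-only peaks and WT peaks were spread unequally over the chromosomes. Against the WT list, HA-BAZ2B-only peaks were over-represented on chromosome 6 (5.43% against 3.14% of peaks, odds ratio 1.77, 1.36 to 2.30; Fisher's exact test, adjusted p = 1.28e-04). They were under-represented on chromosome 17 (7.01% against 9.63%, odds ratio 0.708, 0.594 to 0.844; Fisher's exact test, adjusted p = 0.00111) and on chromosome 19 (5.90% against 8.83%, odds ratio 0.647, 0.538 to 0.779; Fisher's exact test, adjusted p = 1.25e-04). The other chromosomes of the 24 did not pass, and 6 of the 24 had an unadjusted p under 0.05. This contrast leaves out the HA-BAZ2B peaks at WT sites, which by itself widens differences from the WT list. Over all 6794 HA-BAZ2B peaks, the odds ratios against WT were 1.55 (1.20 to 2.00) on chromosome 6, 0.780 (0.663 to 0.917) on 17 and 0.776 (0.655 to 0.919) on 19 (Fisher's exact test, adjusted p = 0.0137, 0.0301 and 0.0301). Against the H3K4me3 list, HA-BAZ2B-only peaks passed Fisher's exact test after adjustment on 0 chromosomes (smallest adjusted p = 0.122), and 4 had an unadjusted p under 0.05. All HA-BAZ2B peaks passed on 2, higher on chromosome 17 (odds ratio 1.27, 1.14 to 1.42) and lower on chromosome 4 (0.699, 0.593 to 0.825; Fisher's exact test, adjusted p = 2.13e-04 for both). The share of H3K4me3 peaks with an HA-BAZ2B peak was 49.7% on chromosome 17 and 28.4% on chromosome 4. WT peaks differed from H3K4me3 peaks on 8 chromosomes by the same test, higher on 15, 17 and 19 and lower on 3, 4, 6, 22 and X. All these contrasts hold only peaks that passed the filter for recurrence, which acted unequally. The WT list kept at most 17.2% of numbered peaks on chromosome 6, 35.9% on 17 and 36.2% on 19. For HA-BAZ2B these shares were at most 38.1%, 54.6% and 46.0%. The contrasts thus do not separate where peaks were called from where they recurred.

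Windows and arms were singled out after their values had been seen. The densest stretches of HA-BAZ2B-only sites were the 1 Mb windows of chromosome 6 from 26000001 to 27000000 (6p22.2, 25 peaks) and from 27000001 to 28000000 (6p22.1, 24 peaks), a region known for the largest cluster of histone genes. These windows also held the most H3K4me3 peaks, 52 and 55, and had 7 and 11 WT peaks. The next were on 16p13.3 (chromosome 16, 2000001 to 3000000), with 19 HA-BAZ2B-only and 42 H3K4me3 peaks, and 16p11.2 (chromosome 16, 30000001 to 31000000), with 18 and 44. WT peaks were densest at 1q23.3 (chromosome 1, 161000001 to 162000000), where 20 WT, 27 HA-BAZ2B and 36 H3K4me3 peaks lay. Light (Giemsa-negative) bands, which are gene-rich, make up 42.2% of the chromosomes. They held 62.5% of HA-BAZ2B-only (61.1 to 63.8%), 60.2% of WT (58.2 to 62.2%) and 60.9% of H3K4me3 peaks (60.2 to 61.7%). The darkest bands make up 16.1% and held 4.87%, 4.69% and 5.73%.

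The share of H3K4me3 peaks that carried an anti-HA peak differed between chromosome arms, and the arms ranked alike in both lines. It was highest for HA-BAZ2B on 16p (51.7%), 20p (51.5%), 17p (51.2%), 17q (49.1%) and 19q (48.96%), and lowest on Xq (27.7%), 4q (27.8%) and 18q (28.7%). For WT it was highest on 19q (24.9%), 17p (24.3%), 20p (19.6%) and 17q (18.9%), and lowest on Xq (6.07%), 18q (6.18%) and 4q (6.41%). On 6p, the share was 40.3% for HA-BAZ2B and 8.33% for WT. Over 41 arms with at least 20 H3K4me3 peaks, the shares of both lines correlated with a Pearson r of 0.870 (permutation p = 1e-05, adjusted p = 1.33e-05 over 4 relations) and a Spearman rho of 0.893 (permutation p = 1e-05, adjusted p = 1e-05). Without the 2 arms farthest from the median, r was 0.879. Part of this is built in, since both shares are taken over the same H3K4me3 peaks and most of those with WT also carry HA-BAZ2B. With the H3K4me3 peaks dealt to the arms at random, r was 0.365 on average and 0.783 at most over 1000 draws, below the observed value (permutation p = 0.001, the smallest these draws can give). With the shares of the lines taken from separate 50% portions of each arm's peaks, r was 0.702 and rho 0.714 on average over 1000 divisions, against 0.00498 and 0.00375 with random arms. All arms come from the same libraries, so they are not independent samples.

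**Figure D3:**
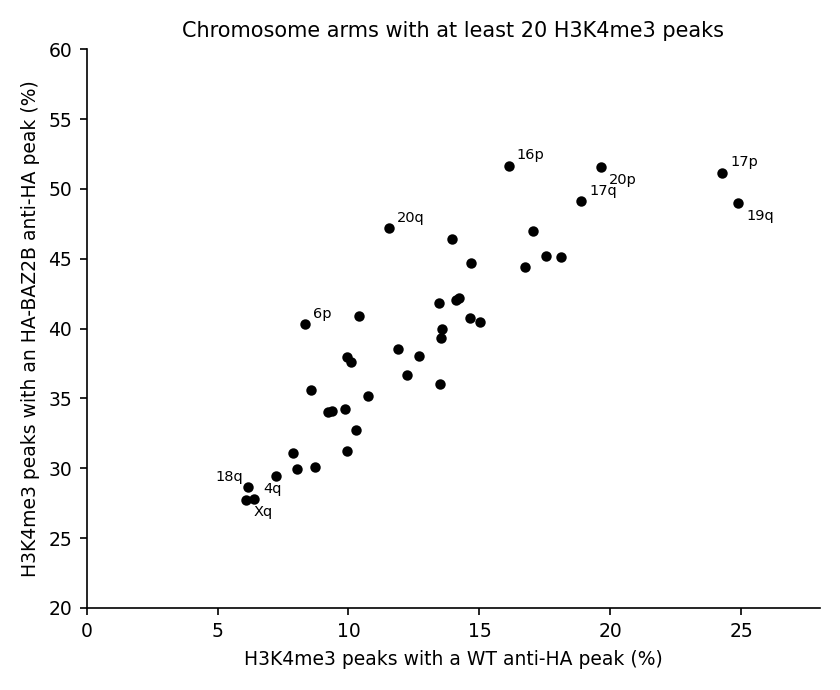
Share of H3K4me3 peaks that overlap an HA-BAZ2B anti-HA peak (%, y axis, which starts at 20) against the share that overlap a WT anti-HA peak (%, x axis); each of the 41 points is 1 chromosome arm with at least 20 H3K4me3 peaks, and arms at the extremes are named. The points rise together from Xq, 4q and 18q to 17p and 19q (rho 0.893).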

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

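Of the tests below, the share of strong tagged peaks without a WT peak, the comparison at the same loci and the haplotype comparison were chosen after related values had been seen, and the fold ranking, the deciles and the rho of −log10 q were set against the depth test only once that test's result was known. At the 1873 places where 1 HA-BAZ2B peak, 1 WT peak and 1 H3K4me3 peak coincided, the HA-BAZ2B and WT lists differed in how closely they followed H3K4me3. The Spearman rho with H3K4me3 fold enrichment was 0.735 for HA-BAZ2B and 0.212 for WT, a difference of 0.523 (permutation test swapping the lists within loci, p = 1e-05, the smallest it can give). For width, rho was 0.883 and 0.357, a difference of 0.526 (permutation p = 1e-05). Each list holds the values of 1 library, and the WT peaks are weaker (median −log10 q 10.3 against 28.5), which alone lowers a rho. H3K4me3 was profiled only in the tagged cells. The comparison is thus within a line for HA-BAZ2B and between lines for WT, and the effect of this on rho was not tested. These p-values therefore describe the 2 lists and not the lines.

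Nearly all anti-HA peaks of both lines lay within H3K4me3 peaks, and none of the explanations tested for this is excluded. H3K4me3 signal carried into the tagged anti-HA library, by mixing of samples or indices, would give a close relation of fold enrichment, and rho over 6556 pairs was 0.742; tagged BAZ2B bound in proportion to H3K4me3 would give the same, and in the untagged library rho was 0.229, between the bounds of 0.2 and 0.5 set beforehand. The untagged background called at greater depth was to show as WT peaks more frequent among the strongest tagged peaks by −log10 q, and they were (32.3% against 26.7%, odds ratio 1.31, 1.18 to 1.46; Fisher's exact test, p = 1.15e-06), with a share of 21.2% in decile 3, 35.9% in the strongest decile and 31.2% in the weakest, which breaks the rise. Other values do not decide on that reading. The tagged peaks without a WT peak had the higher median fold enrichment, by 0.43 (0.144, permutation p = 0.275, with an overlap of at least 50% of the peak). They were narrower and had the lower median −log10 q, 27.9 against 30.3, a difference that was not tested. The −log10 q of paired HA-BAZ2B and WT peaks had a rho of -0.027, while their fold enrichment (0.137) and width (0.291) had positive ones. These pairs hold only peaks called in both lists, and no bound for these rho values was set beforehand. Sites that depend on the tagged BAZ2B stay open as the biological explanation: the 67.7% (65.8 to 69.6%) of the 2389 strongest tagged peaks without a WT peak is the complement of the 32.3% above and no separate evidence.

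Peaks on contigs outside the assembled chromosomes were left out of the report's comparisons. On the alternative MHC haplotypes of chromosome 6, the HA-BAZ2B list had 198 peaks, 2.82% of the list (2.44 to 3.23%), against 22 or 0.898% (0.563 to 1.36%) in the WT list (odds ratio 3.20, 2.06 to 4.98; Fisher's exact test, p = 4.75e-09) and 533 or 3.02% in the H3K4me3 list. On unplaced or unlocalized contigs, the WT list had the larger share, with 33 peaks (1.35%, 0.929 to 1.89%) against 27 (0.384%, 0.253 to 0.559%) in the HA-BAZ2B list. The same reads can map to several of these haplotypes, so the peaks are not separate sites.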

How the results depend on the processing

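The contrasts of all HA-BAZ2B peaks per chromosome were chosen after seeing the data. The 3 overlaps between lists stayed above the shifted lists under all 7 alternatives each (permutation p = 0.001, the smallest the shifts can give). Their ranges were 13.8 to 32.3% for HA-BAZ2B peaks on WT peaks, 63.4 to 99.6% for HA-BAZ2B on H3K4me3 and 29.0 to 94.1% for WT on H3K4me3. The 13.8% came from requiring 50% of the peak. The 63.4% (6794 peaks in each list) and 29.0% (2389 in each) came from limiting both lists of a pair to the length of the shorter one. Merging changed nothing, since no intervals touched. The difference in H3K4me3 overlap between HA-BAZ2B-only and shared peaks no longer passed for −log10 q of at least 5 (odds ratio 0.324, Fisher's exact test, p = 0.0564). Only 26 and 3 peaks lay outside H3K4me3 there. The odds ratio reversed to 1.07 (Fisher's exact test, p = 0.759) with an overlap of at least 50%. Over its settings the Fisher p ran from 1.61e-05 (2389 peaks in each of the 3 lists, odds ratio 0.680) to 0.759. WT peaks covered a median of 48.8% of the HA-BAZ2B peak they matched one to one. The 50% rule thus counted many peaks with a WT overlap as HA-BAZ2B-only, and the shared share fell from 28.7% to 13.8%. How far this change of sets made the reversal was not tested. The difference in fold enrichment shrank to 0.144 (permutation p = 0.275) with that overlap, where the sets changed in the same way, and its cause was not tested further. It stayed past the threshold under the other alternatives run. The number of chromosomes past the threshold went from 3 against WT peaks to 0 against H3K4me3 peaks, by construction another contrast. With all HA-BAZ2B peaks it was 3 against WT and 2 against H3K4me3. Of 53 alternative values, 46 were counted as unchanged, 2 no longer passed, 4 moved and 1 reversed, and 3 of those that moved were median widths under the stricter q. A test was unchanged if its direction and side of the threshold held, a count if it stayed within a set factor, and a median width if it stayed within its main interval. The 46 include the unmerged rows, which repeat the main run, and the unplanned contrasts of all HA-BAZ2B peaks, so the tally does not measure robustness. No paired analysis was possible because the files hold 1 list per group and no value per replicate, and no replicate could be left out for the same reason. Unknown library depth limits every comparison of list lengths. The alternatives for promoter share, G-quadruplex motifs and gene lists were not run.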

Other observations

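The test of untagged-only peaks, the reference values for the arms and the arm relations other than that of HA-BAZ2B with WT shares were chosen after the values had been seen. So was the contrast of chromosome 17 with the other chromosomes. The recurrence filter left unequal shares along the genome. In the WT library, at most 36.2% of numbered peaks were kept on chromosome 19 and 35.9% on chromosome 17, against 17.2% on chromosome 6. In the HA-BAZ2B library, the highest shares were 54.6% on chromosome 17 and 53.9% on chromosome 20, and the lowest was 30.8% on chromosome 4. In the H3K4me3 library, the shares lay between 77.8% on chromosome 18 and 85.4% on chromosome X. The WT list had 4 mitochondrial peaks, the H3K4me3 list 2 and the HA-BAZ2B list 1.

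H3K4me3 peaks on chromosome 17 carried an HA-BAZ2B peak in 49.7% of cases, against 38.9% elsewhere, and a WT peak in 20.4%, against 12.6%. Both shares on chromosome 17 were the highest of any chromosome analysed. The odds ratios below and their interval make no allowance for picking out the highest chromosome. A higher fold enrichment or width of the H3K4me3 peaks on this chromosome is argued against as the whole cause. Within strata of these 2 measures, the odds ratio was 1.63 (1.42 to 1.87), against 1.55 without strata. The −log10 q of the H3K4me3 peaks was not held fixed. Its median was 46.4 on 17p and 46.9 on 17q, against 42.0 over the list, so stronger peaks by that measure stay open. The filter for recurrence was not held fixed either. The HA-BAZ2B library had at least 955 numbered peaks on chromosome 17, beside 1042 H3K4me3 peaks, and 601 on chromosome 4, beside 655. At most 54.6% and 30.8% of these were kept. For WT, at most 35.9% were kept on chromosome 17, against 25.3% over the list. The unequal filter thus stays open as a part of the difference. An arm-wide property that acts on any library, such as DNA copy number, may contribute, since the HA-BAZ2B and WT shares followed each other over 41 arms (Spearman rho 0.893, against 0.340 on average with peaks dealt to arms at random, and 0.714 when no peak enters both shares). After subtracting the mean of each stratum, rho was 0.865 (permutation p = 1e-05, adjusted p = 1e-05 over 4 relations). The median −log10 q of H3K4me3 peaks per arm was also related to the HA-BAZ2B share (Spearman rho 0.727, Pearson r 0.689) and the WT share (rho 0.672, r 0.654), but copy number was not measured, and promoter activity along the arms is an open biological alternative.

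Of the 454 WT peaks without an HA-BAZ2B peak, 145 also lacked H3K4me3. High-copy sequence near centromeres and chromosome ends was tested as a source of these and is left open. In all, 13 of the 145 (8.97%, 4.86 to 14.8%) lay in centromeric or variable bands or within 100 kb of a chromosome end, against 1.152% of H3K4me3 peaks (odds ratio 8.45, 4.70 to 15.2; Fisher's exact test, p = 2.51e-08). The 145 were chosen for lacking H3K4me3, which is rare in such places, so this odds ratio is raised by the choice. The bands together held 11 of the 145 (7.59%, 3.85 to 13.2%) and make up 8.29% of the chromosomes. Of these, centromeric bands held 10 (6.90%, 3.36 to 12.3%) and make up 3.39%. Variable bands held 1 (0.690%) and make up 4.15%. How much of these bands can hold a peak was not examined, so their length does not decide whether there is an excess. No biological explanation was tested.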
